A study of Homo sapiens with 35 samples.

How the data were processed

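Gene expression was measured on human microarrays in 35 samples, each hybridised to 1 array. Normal dermal fibroblasts (NHDF), bone marrow mesenchymal stem cells (Bm MSC) and adipose mesenchymal stem cells (Ad MSC) were grown for 3 days on 4 substrates. Of these, 3 were extracellular matrix laid down beforehand by one of the same cell types, called the Ad, Bm and NHDF matrix here, and the other was tissue culture plastic (TCPS). Per the labels' protocols, cells were seeded at 3500 cells per square centimetre in medium with 20% serum and 1% penicillin and streptomycin. The 12 groups of cell type and substrate held 3 arrays each, except Bm MSC on the Ad matrix, which held 2.

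The deposited values are log2 signals made with RMA, per the submitters' processing notes. RMA subtracts background, brings the arrays to a common distribution and combines the probes of a probe set into 1 value. The software and version used for it are not given in the sources used here. The table held 49495 probe sets on 35 arrays. The array medians lay between 6.27 and 6.34, and single values ran from 2.19 to 14.24. No detection calls were used, and signals close to the lowest values are near background, where differences between samples are compressed. The ERCC control probe sets, which match no transcript of the samples unless such RNA was added, had medians of 3.02 to 3.22 on single arrays.

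Probe sets were named from the platform's annotation. Of the 49495 probe sets, 202 were controls or spike-ins, 45284 had 1 gene symbol, 1333 had several and 2676 further ones had none in the annotation used here. The gene numbers of 45214 probe sets with 1 symbol were found in the reference gene table, which gave current symbols. Probe sets with several symbols were not used. XIST, TSIX and Y-linked genes were left out of every table and test. Transcripts of near-identical genes, such as CXCL1 and CXCL3, the MT1 metallothioneins, replication-dependent histones and HLA genes, can bind the same probes, so their separate values are uncertain. No genome build was used, and no coordinates are given.

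Before the filter, 18216 genes had a probe set of 1 symbol. A probe set was kept when it lay above its array's own median on at least 2 arrays, and for each gene the kept probe set with the highest mean over all arrays was tested. This left 11120 genes. The deposited values were not normalized further for the reported results. A single limma model with the 12 group means was fitted to all 35 arrays, followed by eBayes, with 23 residual and 5.143 prior degrees of freedom per gene. For single genes, an adjusted p is from limma's moderated test, two-sided, with the Benjamini-Hochberg correction over the 11120 genes, and a gene was called changed at an adjusted p under 0.05. Folds are 2 to the power of the size of a log2 difference, and SE is the standard error of that difference.

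The contrasts were fixed before the data were examined, as were the gene lists, the alternatives and the rule for naming genes. Within each cell type, the mean of the 3 matrix groups was compared with plastic, each matrix was compared with plastic, the 3 matrices were compared with one another by a moderated F-test, and the cells' own matrix was compared with the mean of the other matrices. Cell types were compared in pairs over the mean of their 4 substrate groups. The difference between cell types in their response to the matrices was tested by an interaction contrast. Genes changed in the same direction in all 3 cell types were counted. A test for transcripts left behind by the source cells took the 100 genes that stood highest in the source cell type over the receiving cell type on plastic. It asked whether they were higher in the receiving cells on the source's matrix than on the cells' own matrix.

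In all, 44 gene lists with 899 genes were fixed, of which 824 genes were on the array and 43 lists had at least 3 tested members. Lists were tested with camera from limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with the Benjamini-Hochberg correction over the lists of a contrast. The same test with the correlation estimated from the data stands beside it. List members were counted both with the adjustment over all genes and adjusted over the list alone.

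Named genes followed 1 rule. For the matrices against plastic, it took the 10 largest rises and 10 largest falls among called genes whose matrix arrays all lay on 1 side of every plastic array. For pairs of cell types it took the 6 largest on either side in the same way. For the differences among matrices, the own matrix and the interaction it took the 5 smallest adjusted p-values. For a list past camera it took up to 4 members with the largest called change, or 3 for cell type pairs. For genes changed alike it took the 10 whose smallest change over the cell types was largest. Uncharacterised and small RNA symbols were passed over.

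Technical signs were read from the arrays. These were the mean of the poly-A spike-ins, which are control RNAs usually added in a fixed amount, the ribosomal RNA probe sets, the SD over all named probe sets (called the spread here), the background controls, the hybridisation controls and the difference between the 3-prime and 5-prime GAPDH probe sets. Matrix arrays were compared with plastic arrays on each by exact permutation tests, two-sided, with adjustment over 18 tests. The smallest p-value these tests can give is 0.00455 with 9 against 3 arrays and 0.00606 with 8 against 3.

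The fit and the list test were tried in 5 simulations with 200 of the 11120 genes changed. For the matrices against plastic in Bm MSC, 61.2% of genes changed 1.2-fold and 100% of those changed 1.5-fold or more were recovered, and 5.64% of called genes were false. For the NHDF matrix alone (3 against 3 arrays), 42.8% at 1.2-fold and 98.4% at 1.5-fold were recovered. A shifted list was found in 5 of 5. These rates are for simulated noise, not real arrays.

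The alternatives tried were no filter and a stricter filter (above the 60th percentile on 3 arrays), the mean of a gene's probe sets, quantile normalization on top, centring each array on its median, eBayes with trend and robust, array weights, the replicate number as a block, a fit to the arrays of the compared cell types alone, a fold of at least 1.5 as well, camera with an estimated correlation, fry (which asks whether a list's genes move one way without comparing them with other genes), source lists of 50 and 200 genes, and each array left out in turn. Added after seeing the data were 3 more: the array spread as a covariate, the poly-A spike-in signal as a covariate, and a fit without the 5 arrays with the highest background signal.

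The titles call the arrays of a group biological replicates, without saying whether they came from separate cultures or donors. The p-values measure the spread between these arrays. Neither cell type nor matrix source can be told apart from its donor or lot. The number of arrays limits the precision. Software was R 4.3.3 with limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.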

Results

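The 35 arrays covered 3 human mesenchymal cell types on 4 substrates. NHDF are fibroblasts of the skin. Mesenchymal stem cells are adherent stromal cells that can form bone, cartilage and fat, here from bone marrow (Bm MSC) or adipose tissue (Ad MSC). Each cell type was grown on matrix laid down by each of the 3 cell types and on plastic, so the design asked how a cell-derived matrix changes expression, whether its source matters, and whether the cell types respond alike. The groups held 3 arrays each, except 2 for Bm MSC on the Ad matrix, which gave 9, 8 and 9 matrix arrays against 3 plastic arrays in NHDF, Bm MSC and Ad MSC. Pearson's r across probe sets between arrays of a group was 0.991 to 0.9977 in NHDF, 0.9951 to 0.998 in Bm MSC and 0.9939 to 0.9976 in Ad MSC. The first principal components separated the cell types: component 1 held 51.6% of the variance and component 2 held 31%, with 99.1% and 99.5% of each lying between cell types. Component 3 held 7.2%, of which 69.6% lay between matrices and plastic. The poly-A spike-in signal differed between cell types, with means of 6.57 ± 0.19 in NHDF (SD, n = 12), 8.16 ± 0.21 in Bm MSC (n = 11) and 6.89 ± 0.37 in Ad MSC (n = 12).

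In NHDF, contractile genes were lower on the cell-derived matrices than on plastic, and fibrillar collagens were too by camera, a call lost with an estimated correlation (adjusted p = 0.153). The gene for cardiac actin, ACTC1, was 2.94-fold lower (log2 -1.56, SE 0.16), smooth muscle actin ACTA2 2.04-fold lower (log2 -1.03) and MYOCD, a coactivator of smooth muscle genes, 3.11-fold lower (log2 -1.64, SE 0.13, adjusted p = 1.8e-10). Without the filter on dim signals, another MYOCD probe set stood in for it and its change was not called (log2 -0.16, adjusted p = 0.326). ELN, which encodes elastin, was 2.46-fold lower (log2 -1.3, SE 0.11) and IL6, an inflammatory cytokine, also 2.46-fold lower (log2 -1.3, SE 0.1, adjusted p = 3.7e-10). Among the largest rises were GPAT3, an enzyme of glycerolipid synthesis, at 3.28-fold (log2 1.72, SE 0.11, adjusted p = 2.3e-11), IL13RA2 at 2.42-fold and the transcription factor ETV1 at 2.37-fold. All values in this comparison are from 9 matrix arrays against 3 plastic arrays.

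The other genes of the largest rises in NHDF were CNIH3 (2.33-fold), DOCK4 (2.2-fold), RGS17 (2.12-fold), NTNG1 (2.07-fold), ABTB3 (1.99-fold), RGS20 (1.98-fold) and SPHKAP (1.97-fold). Without the filter the rise of SPHKAP was not called (log2 0.02, adjusted p = 0.916). The other large falls were GFRA1, a receptor subunit for the ligand GDNF (3.15-fold, log2 -1.66), DIO2, which activates thyroid hormone (2.95-fold), SULF1 (2.53-fold), HSPB3 (2.13-fold), ANKRD1 (2.13-fold) and ALDH1A1 (2.04-fold).

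By list, 14 of 20 contractile genes fell in NHDF, 1 rose and 5 did not pass (16 fell and 1 rose adjusted over the list alone), with a median log2 of -0.31 and an adjusted p of 3.4e-18 in camera (adjusted p = 0.000406 with an estimated correlation). Of 25 targets of the mechanosensitive coactivators YAP and TAZ, 12 fell and 3 rose (12 and 4 adjusted over the list alone), among them IGFBP3 (log2 -0.98), F3 (-0.9) and CCN2 (-0.55), with adjusted p = 1.2e-06 and 0.0173 with an estimated correlation. Of 24 focal adhesion genes 5 fell and 3 rose (11 and 3 adjusted over the list alone), FERMT2 (-0.49) and TNS3 (-0.45) among those that fell (adjusted p = 0.00057, and 0.00721 with an estimated correlation). Of 20 growth factors 5 fell and 1 rose (6 and 3 adjusted over the list alone), with LIF at -0.6 and FGF2 at -0.53 (adjusted p = 0.00231, and 0.013 with an estimated correlation). Mesodermal patterning factors went the other way. Of 20 such genes 10 rose and 0 fell in limma (13 and 1 adjusted over the list alone), led by MEOX2 at 1.74-fold (log2 0.8) and TBX2 (log2 0.5), with adjusted p = 0.00051 and 0.0308 with an estimated correlation.

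The remaining lists past camera in NHDF lost the call with an estimated correlation. Fibrillar collagens, the main fibre-forming collagens, fell in 5 of 8 genes and rose in 0 (6 and 0 adjusted over the list alone), with COL11A1 at -0.76, COL1A2 at -0.42 and COL5A2 at -0.38 (adjusted p = 5.8e-05, and 0.153 with an estimated correlation). The call of COL1A2 ended with the mean of its probe sets (adjusted p = 0.0544). Of 27 elastic fibre and matricellular genes 9 fell and 4 rose (11 and 5 adjusted over the list alone), with EFEMP1 at -1.01, POSTN at -0.99 and LTBP1 at 0.95 (adjusted p = 0.00365, and 0.487 with an estimated correlation). Collagen processing genes fell in 7 of 19, LOX (-0.4) and TGM2 (-0.52) included, and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.00102, and 0.422 with an estimated correlation). Chemokines and cytokines fell in 5 of 21, CCL2 among them (-0.93), and CXCL3 rose (0.5), with 9 and 2 adjusted over the list alone (adjusted p = 0.00666, and 0.309 with an estimated correlation).

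Proteoglycan genes in NHDF fell in 5 of 19 and rose in 4 (8 and 4 adjusted over the list alone), with ACAN at -0.87 and LUM at -0.63 (adjusted p = 0.0392, and 0.418 with an estimated correlation). Metallothioneins fell in 2 of 9, MT1F (-0.33) and MT1X (-0.21), with 3 adjusted over the list alone (adjusted p = 0.00853, and 0.153 with an estimated correlation). Both calls ended without plastic array 3 (adjusted p = 0.138 and 0.1), as did that of MT1X without plastic array 2 (adjusted p = 0.0531) and that of MT1F without the 5 arrays of highest background (adjusted p = 0.0856). Basement membrane genes fell in 2 of 15 and rose in 0 (the same adjusted over the list alone; adjusted p = 0.0235, and 0.527 with an estimated correlation), and their median of -0.04 became 0.03 with the poly-A signal as a covariate. Matrix proteases and their inhibitors rose in 8 of 19 and fell in 1 (likewise adjusted over the list alone), with MMP1, a collagenase, at 1.65-fold, PLAU at 1.64-fold and CTSK at 1.59-fold (adjusted p = 0.00057, and 0.418 with an estimated correlation). Targets of p53 rose in 7 of 20 and fell in 0 (likewise adjusted over the list alone), TP53INP1 among them (log2 0.46; adjusted p = 0.00057, and 0.127 with an estimated correlation).

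Across all genes, limma called 1546 of 11120 in NHDF, 1021 higher and 525 lower on the matrices, and 3466 had an unadjusted p under 0.05. At a fold of at least 1.5 there were 66 higher and 59 lower. With quantile normalization on top the split was 773 higher and 771 lower. Of all genes, 544 were higher and 319 lower on every matrix array than on every plastic array, where chance gives 0.909%. Leaving out plastic array 2 or 3 left 783 or 642 called genes. The ribosomal RNA probe sets were 0.39 higher (log2) on the matrix arrays than on plastic, with an exact permutation p of 0.0273 (adjusted p = 0.0983).

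In Bm MSC, MMP1 and several chemokines of the CXC family, which attract neutrophils, were among the most raised genes on the matrices. MMP1 was 8.35-fold higher (log2 3.06, SE 0.08, adjusted p = 2.4e-22, 8 matrix and 3 plastic arrays), CXCL8 5.64-fold (log2 2.5, SE 0.1, adjusted p = 2.9e-17), CXCL3 4.8-fold (log2 2.26) and CXCL1 3.91-fold (log2 1.97, SE 0.08). ACTC1 was 5.75-fold lower (log2 -2.52, SE 0.16), ACAN, which encodes the cartilage proteoglycan aggrecan, 4.95-fold lower (log2 -2.31, SE 0.13) and CEMIP, which takes part in hyaluronan breakdown, 4.64-fold lower (log2 -2.21). COL4A1, a collagen of basement membranes, was 3.69-fold lower (log2 -1.88). The other large rises were GPAT3 (4.48-fold), IGF2BP3 (3.84-fold), ITGA2 (3.22-fold), ETV1 (3.14-fold), PTGER4 (2.99-fold) and the secreted Wnt modulator SFRP1 (2.96-fold), and the other large falls included DDIT4 (3.56-fold), FNDC1 (3.54-fold), INHBB (3.27-fold) and SCRG1 (3.06-fold).

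Several lists of matrix genes fell in Bm MSC. Of 8 fibrillar collagens 6 fell and 0 rose (the same adjusted over the list alone), with a median of -0.73, COL11A1 2.02-fold, COL1A1 1.98-fold and COL5A1 1.78-fold lower (adjusted p = 3.4e-08, and 0.0405 with an estimated correlation). Of 27 elastic fibre and matricellular genes 21 fell and 0 rose (the same adjusted over the list alone), with ELN 2.74-fold, MFAP5 2.27-fold and EFEMP1 1.99-fold lower (adjusted p = 8.3e-14, and 0.037 with an estimated correlation). Of 19 proteoglycan genes 11 fell and 3 rose (the same adjusted over the list alone), LUM being 2.54-fold lower and SDC1 higher by a log2 of 0.74 (adjusted p = 2.1e-06, and 0.037 with an estimated correlation). Contractile genes fell in 15 of 20 and rose in 2 (15 and 3 adjusted over the list alone), with ACTA2 2.91-fold and CNN1 2.84-fold lower and TAGLN3 2.76-fold higher (adjusted p = 3.6e-12, and 0.00563 with an estimated correlation). Focal adhesion genes fell in 11 of 24, TNS1 1.5-fold, and rose in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.000195, and 0.00563 with an estimated correlation).

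Stress and metabolic lists also fell in Bm MSC. Of 22 genes of the unfolded protein response 13 fell and 0 rose (the same adjusted over the list alone), with the asparagine synthetase ASNS 2.04-fold and CHAC1 1.76-fold lower (adjusted p = 1.4e-08, and 0.0245 with an estimated correlation). Of 23 hypoxia and glycolysis genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), with hexokinase HK2 1.47-fold and the glucose transporter SLC2A1 1.36-fold lower (adjusted p = 2.5e-06, and 0.012 with an estimated correlation).

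For 8 lists in Bm MSC the call was lost with an estimated correlation. Cell cycle genes rose in 28 of 35 and fell in 0 (30 and 0 adjusted over the list alone), with CDC20 1.34-fold higher (log2 0.42), BUB1 0.41 and FOXM1 0.4 (adjusted p = 1.2e-07, and 0.137 with an estimated correlation). Chemokines and cytokines rose in 9 of 21 and fell in 2 (the same adjusted over the list alone), CXCL6 being 2.5-fold higher (adjusted p = 0.0221, and 0.273 with an estimated correlation). Collagen processing genes fell in 13 of 19 and rose in 0 (the same adjusted over the list alone), the cross-linking enzyme LOX by 1.55-fold (adjusted p = 2.9e-10, and 0.0806 with an estimated correlation). Basement membrane genes fell in 8 of 15 and rose in 1 (10 and 1 adjusted over the list alone), COL4A2 2.28-fold and HSPG2 1.44-fold lower, LAMA4 higher by 0.44 (adjusted p = 1.6e-05, and 0.178 with an estimated correlation). Pericyte markers fell in 6 of 8 and rose in 2 (the same adjusted over the list alone), MCAM 1.75-fold lower and ABCC9 higher by 0.76 (adjusted p = 0.0221, and 0.101 with an estimated correlation). Surface markers of mesenchymal stromal cells fell in 6 of 15 and rose in 2 (the same adjusted over the list alone; adjusted p = 0.00865, and 0.311 with an estimated correlation). YAP and TAZ targets fell in 11 of 25 and rose in 4 (the same adjusted over the list alone), CCN2 by 1.35-fold (adjusted p = 0.0198, and 0.217 with an estimated correlation). TGF-beta response genes fell in 7 of 23, TGFBI by 1.43-fold, and rose in 2 (7 and 4 adjusted over the list alone; adjusted p = 0.025, and 0.171 with an estimated correlation).

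Over all genes, limma called 4316 in Bm MSC, 3109 higher and 1207 lower, and 5485 had an unadjusted p under 0.05. At least 1.5-fold changes numbered 154 higher and 136 lower. With quantile normalization on top there were 2123 higher and 1441 lower. Of all genes, 2087 were higher and 688 lower on every matrix array than on every plastic array, where chance gives 1.21%. Leaving out plastic array 2 left 2597 called genes, and the array spread as a covariate left 2357. Ribosomal RNA probe sets were 0.385 higher on the matrix arrays (exact permutation p = 0.00606, the smallest possible, adjusted p = 0.0983), and the array spread was 0.045 higher (exact permutation p = 0.0242, adjusted p = 0.0983).

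In Ad MSC, ACTC1 had the largest change, 15.6-fold lower on the matrices than on plastic (log2 -3.97, SE 0.16, adjusted p = 1.3e-17, 9 matrix and 3 plastic arrays). PRR15 was 6.35-fold lower (log2 -2.67, SE 0.1), SCRG1 6.33-fold (log2 -2.66, SE 0.11), DDIT4, an inhibitor of mTORC1 signalling induced by stress, 4.85-fold (log2 -2.28), and COL4A1 4.51-fold (log2 -2.17). COMP, a protein of cartilage matrix, was 3.61-fold lower (log2 -1.85, SE 0.12), and MEX3B, PI16, CEMIP and TPD52L1 were 4.65-fold, 4.33-fold, 4.16-fold and 3.95-fold lower. The largest rises were GPAT3 at 3.63-fold (log2 1.86, SE 0.11), IL13RA2 at 3.61-fold and CRYBG1 at 3.26-fold, and MMP1 rose 3-fold (log2 1.58, SE 0.07). CNIH3 (3.25-fold), TMEM158 (3.08-fold), COLEC12 (2.97-fold), ADGRG1 (2.94-fold) and CXCL3 (2.94-fold) rose as well.

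Of 23 TGF-beta response genes in Ad MSC, 16 fell and 2 rose (the same adjusted over the list alone), with the cell cycle inhibitor CDKN2B 2.08-fold, IGFBP3 2-fold and TGFBI 1.58-fold lower (median -0.23, adjusted p = 1.7e-08, and 0.00399 with an estimated correlation). Elastic fibre genes fell in 19 of 27 and rose in 1 (the same adjusted over the list alone), with ELN 3.19-fold and EFEMP1 2.7-fold lower (adjusted p = 3.9e-13, and 0.0478 with an estimated correlation). Contractile genes fell in 12 of 20 and rose in 3 (the same adjusted over the list alone), with CNN1 1.84-fold and TAGLN 1.67-fold lower and TAGLN3 2.85-fold higher (adjusted p = 3.2e-07, and 0.0478 with an estimated correlation). Chondrogenic genes fell in 4 of 6 and rose in 1 (the same adjusted over the list alone), with ACAN 3.19-fold and HAPLN1 3.02-fold lower and SOX9, a transcription factor of cartilage, 1.53-fold higher (median -0.92, adjusted p = 0.0019, and 0.0478 with an estimated correlation). Unfolded protein response genes fell in 10 of 22 and rose in 3 (the same adjusted over the list alone), ASNS 2.96-fold and TRIB3 1.98-fold lower (adjusted p = 9.1e-07, and 0.0478 with an estimated correlation). Hypoxia and glycolysis genes fell in 10 of 23 and rose in 3 (11 and 3 adjusted over the list alone), ANKRD37 2.76-fold and SLC2A1 1.5-fold lower (adjusted p = 0.000233, and 0.0478 with an estimated correlation).

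The other 10 lists past camera in Ad MSC lost the call with an estimated correlation. Cell cycle genes rose in 27 of 35 and fell in 0 (31 and 0 adjusted over the list alone), with CDC20 1.43-fold and the proliferation marker MKI67 1.4-fold higher (adjusted p = 2e-10, and 0.0743 with an estimated correlation). Fibrillar collagens fell in 6 of 8 and rose in 0 (the same adjusted over the list alone), COL11A1 2.76-fold and COL1A1 2.06-fold lower (adjusted p = 9.1e-07, and 0.0743 with an estimated correlation). Collagen processing genes fell in 13 of 19, TGM2 2.2-fold and P4HA1 1.65-fold, and rose in 2 (13 and 3 adjusted over the list alone; adjusted p = 1.1e-08, and 0.0942 with an estimated correlation). Basement membrane genes fell in 9 of 15, COL4A2 2.43-fold and NID2 1.81-fold, and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 1.8e-06, and 0.137 with an estimated correlation). Proteoglycans fell in 10 of 19, LUM 2.71-fold, and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 9e-05, and 0.078 with an estimated correlation). YAP and TAZ targets fell in 12 of 25, ANKRD1 3.61-fold and CCN2 1.71-fold, and rose in 5 (the same adjusted over the list alone; adjusted p = 0.000912, and 0.0942 with an estimated correlation). Complement genes fell in 5 of 7, C1S 1.63-fold, and rose in 0 (the same adjusted over the list alone; adjusted p = 0.00421, and 0.122 with an estimated correlation).

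Immediate early genes in Ad MSC moved both ways: 9 of 21 fell and 4 rose (11 and 4 adjusted over the list alone), with the phosphatase DUSP2 at -1.13 and FOS at -0.83 (SE 0.21) against DUSP6 at 0.93 and DUSP5 at 0.7 (adjusted p = 0.0353, and 0.271 with an estimated correlation). Surface markers of mesenchymal stromal cells fell in 6 of 15, MCAM 1.67-fold, and rose in 3, NES by 0.76 (the same adjusted over the list alone; adjusted p = 0.0392, and 0.445 with an estimated correlation). Lysosome genes fell in 6 of 19, HEXA by a log2 of -0.3, and rose in 2 (the same adjusted over the list alone; adjusted p = 0.0435, and 0.455 with an estimated correlation).

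Limma called 4378 genes in Ad MSC, 3010 higher and 1368 lower, and 5186 had an unadjusted p under 0.05. At least 1.5-fold changes numbered 125 higher and 243 lower. Of all genes, 1830 were higher and 954 lower on every matrix array than on every plastic array, where chance gives 0.909%. The background controls were 0.023 higher on the matrix arrays (exact permutation p = 0.0182, adjusted p = 0.0983), and the 3-prime to 5-prime difference of GAPDH was 0.039 higher (exact permutation p = 0.0273, adjusted p = 0.0983).

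**Figure D1:**
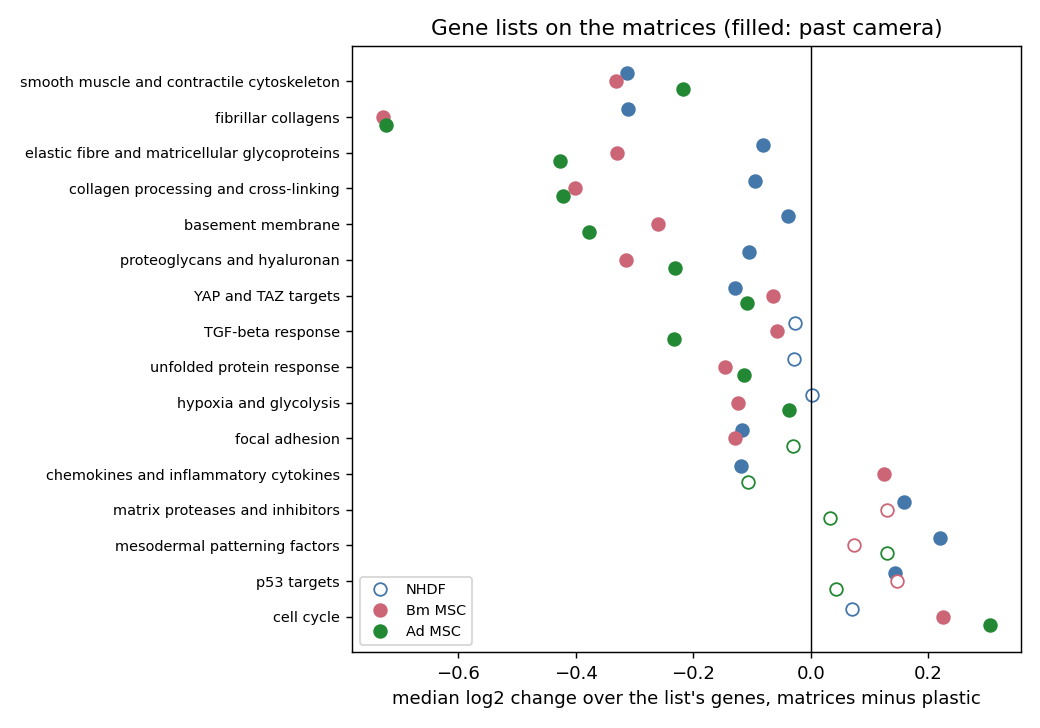
Median log2 change of 16 gene lists, matrices minus plastic (x axis), with 1 point per cell type coloured as in the key and filled where the list passed camera. Contractile genes and fibrillar collagens lay below 0 in the 3 cell types, with medians of -0.31, -0.33 and -0.22 and of -0.31, -0.73 and -0.72 in NHDF, Bm MSC and Ad MSC, while the median of hypoxia and glycolysis in NHDF, at 0.001, turned to -0.002 and -0.016 with quantile normalization and median centring.

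Some genes changed in the same direction on the matrices in all 3 cell types. GPAT3 was 3.28-fold, 4.48-fold and 3.63-fold higher in NHDF, Bm MSC and Ad MSC, and ETV1 2.37-fold, 3.14-fold and 2.15-fold higher. ELN was 2.46-fold, 2.74-fold and 3.19-fold lower, and COL4A1 2.03-fold, 3.69-fold and 4.51-fold lower. The other named genes of this kind were RGS20 and ADGRG1, which rose by at least 1.98-fold and 1.92-fold in each cell type, and ACTC1, ANKRD1, EFEMP1 and CEMIP, which fell by at least 2.94-fold, 2-fold, 1.99-fold and 1.91-fold.

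In all, 752 genes were called in the 3 cell types with 1 sign, 508 higher and 244 lower, where 84.3 would be expected from the product of the shares called. Another 40 were called in all 3 with mixed signs. No array is shared between cell types. With quantile normalization on top the split was 361 higher and 327 lower, and with the array spread as a covariate the number fell to 493. Leaving out plastic array 2 or 3 of NHDF gave 460 or 386. In both Bm MSC and NHDF, 671 genes were higher and 306 lower (285 and 57 expected if calls were independent). In Ad MSC and NHDF the numbers were 619 and 316 (276 and 64.6), and in Bm MSC and Ad MSC 1984 and 572 (842 and 148).

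**Figure D2:**
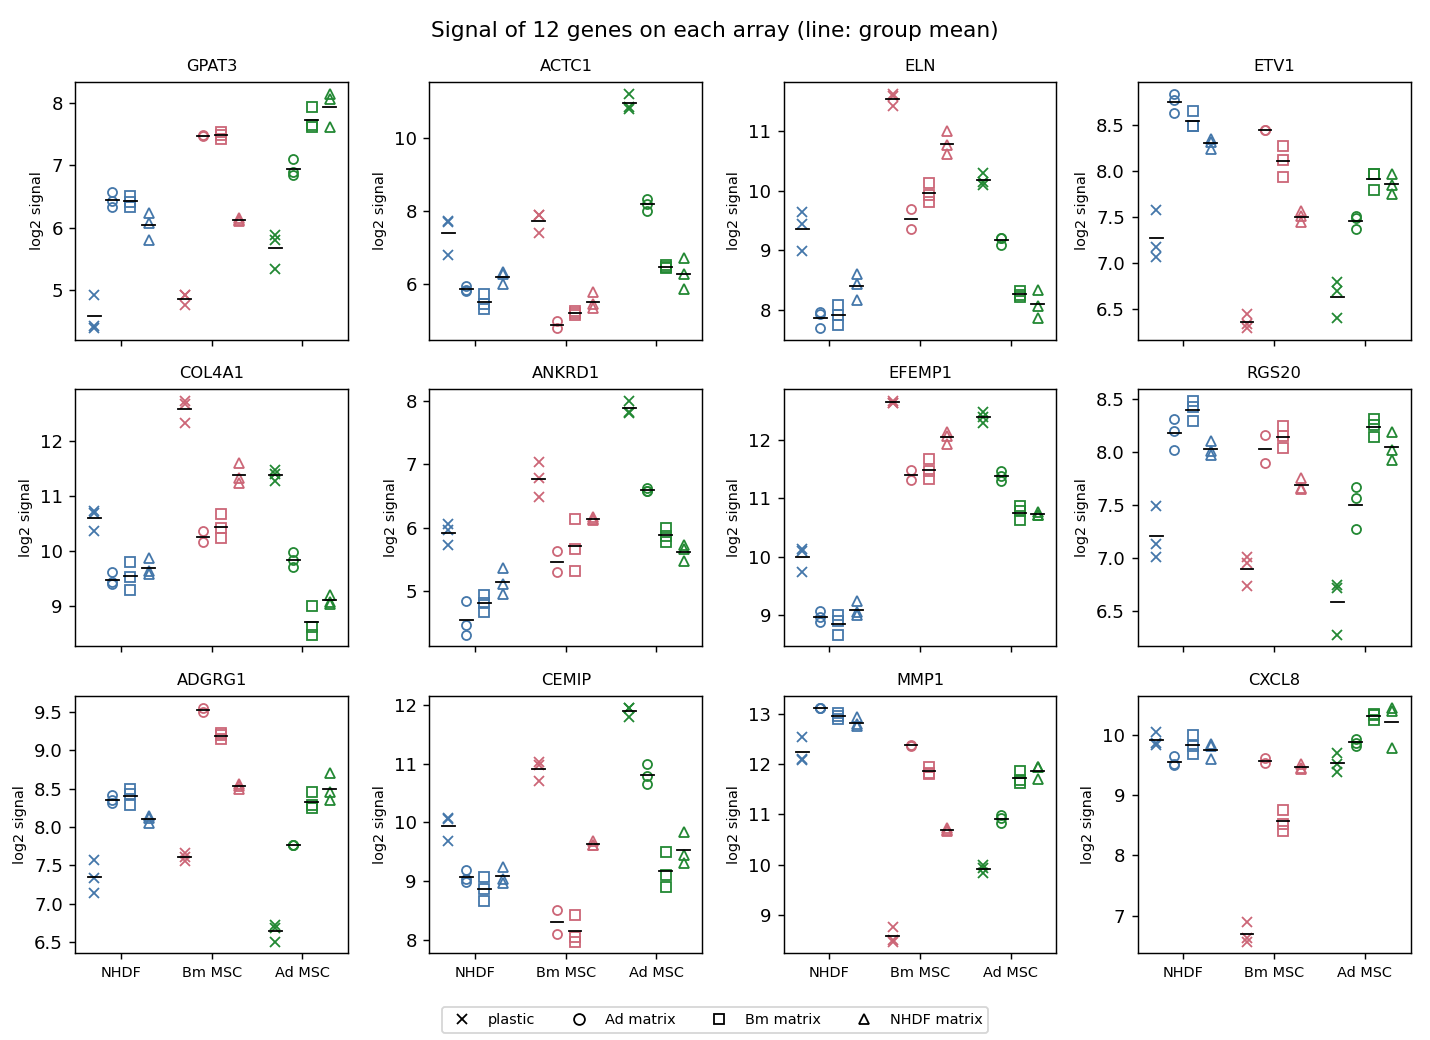
Log2 signal (y axis) of 12 genes on each array (points) by cell type and substrate, with a line at each group mean. GPAT3 lay higher on the matrices than on plastic in each cell type, by 3.28-fold, 4.48-fold and 3.63-fold in NHDF, Bm MSC and Ad MSC, while CXCL8 rose 5.64-fold in Bm MSC and 1.52-fold in Ad MSC and had a log2 difference of -0.2 in NHDF (adjusted p = 0.16).

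The cell types differed in how strongly single genes responded to the matrices, as tested by the interaction. Between Bm MSC and NHDF, MMP1 rose 5.06-fold more in Bm MSC (log2 2.34, SE 0.11, adjusted p = 3.5e-15), CXCL8 6.49-fold more (log2 2.7, SE 0.14) and CXCL1 3.48-fold more (log2 1.8, SE 0.11). On plastic MMP1 already had a mean log2 signal of 12.24 in NHDF, where bright signals can be compressed, against 8.58 in Bm MSC, so the fold difference for it is uncertain. The RNA-binding protein gene IGF2BP3 rose 2.94-fold more and CAMK2N1 2.54-fold more. In NHDF, the changes of CXCL8 (log2 -0.2, adjusted p = 0.16) and CXCL1 (0.17, adjusted p = 0.14) did not pass. In total 829 genes differed, 536 with a higher and 293 with a lower matrix effect in Bm MSC, and at a fold of at least 1.5 the split was 79 and 81. Of 21 chemokines and cytokines 9 had a higher and 1 a lower effect in Bm MSC (11 and 1 adjusted over the list alone; adjusted p = 2.7e-10, and 0.0148 with an estimated correlation). Of 23 hypoxia and glycolysis genes 7 had a lower and 1 a higher effect (8 and 1 adjusted over the list alone; adjusted p = 1.1e-05, and 0.0279 with an estimated correlation). In all, 17 lists passed camera and 2 kept the call with an estimated correlation. Matrix proteases passed downward with a median of -0.08 and a mean of 0.02. Leaving out plastic array 2 of Bm MSC lowered the gene count to 537.

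Between Ad MSC and NHDF, SCRG1 fell 5.73-fold more in Ad MSC (log2 -2.52, SE 0.15, adjusted p = 1.6e-12), PRR15 5.39-fold more (log2 -2.43, SE 0.15) and MEX3B 3.85-fold more (log2 -1.94, SE 0.11). TSC22D3, a glucocorticoid-induced gene, was 2.4-fold lower on the matrices in Ad MSC and had a log2 change of 0.05 in NHDF (adjusted p = 0.62), a 2.48-fold difference. ANKRD37 fell 2.36-fold more. Of 1526 genes that differed, 780 had a higher and 746 a lower effect in Ad MSC, but the split was 61 and 187 at a fold of at least 1.5. It was 1326 and 849 with the array spread and 1140 and 709 with the poly-A signal as a covariate. TGF-beta response genes had a lower effect in Ad MSC in 8 of 23 genes and a higher one in 0 (10 and 0 adjusted over the list alone; adjusted p = 1.2e-06, and 0.0105 with an estimated correlation). Chondrogenic genes did so in 3 of 6 and in 0 the other way (4 and 0 adjusted over the list alone; adjusted p = 9.6e-05, and 0.0105 with an estimated correlation). Cell cycle genes had a higher effect in Ad MSC in 16 of 35 genes and a lower one in 0 (23 and 0 adjusted over the list alone; adjusted p = 1.6e-10, and 0.0912 with an estimated correlation). In all, 18 lists passed camera and 2 kept the call with an estimated correlation. Fibril-associated collagens passed downward with a median of 0.02 and a mean of -0.24.

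Between the mesenchymal stem cells, the matrix effect on PI16 differed 3.8-fold (log2 1.92), with a 4.33-fold fall in Ad MSC against a log2 change of -0.19 in Bm MSC (adjusted p = 0.1). SFRP1 rose 2.96-fold in Bm MSC and had a log2 change of -0.09 in Ad MSC (adjusted p = 0.37), a 3.15-fold difference. ATF5, a transcription factor of the stress response, fell 2.29-fold in Ad MSC and rose 1.14-fold in Bm MSC. The effect on MEX3B and MMP1 differed 2.86-fold and 2.79-fold. In total 697 genes differed, 478 higher and 219 lower in Bm MSC, a split of 463 and 389 with the array spread as a covariate, 471 and 320 with quantile normalization on top and 141 and 47 at a fold of at least 1.5. TGF-beta response genes had a higher effect in Bm MSC in 9 of 23 genes and a lower one in 1 (10 and 2 adjusted over the list alone; adjusted p = 2.2e-05, and 0.0189 with an estimated correlation). Chemokines and cytokines had a higher effect in 10 of 21 and a lower one in 2 (13 and 2 adjusted over the list alone; adjusted p = 3.7e-09, and 0.0189 with an estimated correlation). In all, 9 lists passed camera and 2 kept the call with an estimated correlation. Without plastic array 2 of Bm MSC 463 genes were called, and without plastic array 3 of Bm MSC or plastic array 2 of Ad MSC only 4 lists passed.

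Single genes differed between the matrices, with chance not excluded for the NHDF count. In Bm MSC, MMP1 had a mean log2 signal of 12.37 on the Ad matrix, 11.85 on the Bm matrix, 10.69 on the NHDF matrix and 8.58 on plastic (adjusted p = 8.8e-12 among the matrices in limma's F-test), and IGF2BP3 7.83, 7.78, 6.73 and 5.5 (adjusted p = 3e-10). In Ad MSC, PRR15 had 6.07, 4.54, 4.37 and 7.66 (adjusted p = 3.6e-10), MEST, an imprinted gene, 8.74, 7.91, 7.72 and 9.44 (adjusted p = 2.4e-10), and the oxytocin receptor gene OXTR 9.19, 8.32, 8.1 and 10.21 (adjusted p = 1.1e-08). In NHDF, TCIM had 7.06, 6.07, 6.42 and 6.56 (adjusted p = 1.6e-05), and INSIG1, a regulator of cholesterol synthesis, 9.1, 8.9, 9.54 and 9.09 (adjusted p = 1.6e-05). KRTAP2-3, PNRC1 and ARMCX2 in NHDF, PSG5, CAMK2N1 and KRT7 in Bm MSC, and CEMIP and MMP1 in Ad MSC completed the genes with the smallest adjusted p. The calls of PNRC1 and ARMCX2 ended without the 5 arrays of highest background (adjusted p = 0.22 and 0.278), and that of ARMCX2 in a fit to the NHDF arrays alone (adjusted p = 0.081).

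The F-test called 1722 genes among the matrices in NHDF, 1739 in Bm MSC and 1018 in Ad MSC. In NHDF the count rested on single arrays: it was 205 and 276 without array 2 or 3 on the Bm matrix, 889 and 1109 without array 1 or 3 on the NHDF matrix and 3564 without array 1 on the Bm matrix. It was 4 in a fit to the NHDF arrays alone and 19 without the 5 arrays of highest background. In Bm MSC it was 967 and 734 without array 1 or 2 on the Ad matrix and 784 without array 2 on the Bm matrix. In Ad MSC it was 368 and 394 without array 1 or 2 on the Bm matrix and 457 and 431 without array 2 or 3 on the Ad matrix.

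Against plastic, the Bm matrix had the most called genes in each cell type. In NHDF these were 3577 genes (2306 higher, 1271 lower), against 1359 on the Ad matrix (932 higher, 427 lower) and 442 on the NHDF matrix (210 higher, 232 lower). In Bm MSC they were 5751 (4083 higher, 1668 lower), against 2224 on the Ad matrix, with 2 arrays (1466 higher, 758 lower), and 1442 on the NHDF matrix (1097 higher, 345 lower). In Ad MSC they were 4811 (3313 higher, 1498 lower), against 1938 on the Ad matrix (1274 higher, 664 lower) and 3594 on the NHDF matrix (2343 higher, 1251 lower). With quantile normalization on top the splits were 1709 higher and 1852 lower for NHDF on the Bm matrix, 650 and 641 on the Ad matrix, 2745 and 2073 for Bm MSC on the Bm matrix and 763 and 437 on the NHDF matrix. With the array spread as a covariate Bm MSC had 2612 genes on the Bm matrix against 2243 on the Ad matrix, and 868 on the NHDF matrix. Median centring gave 1775 and 1617 for NHDF on the Bm matrix. At a fold of at least 1.5 the lead was smaller, with 206 genes on the Bm matrix against 163 on the next in NHDF, 455 against 414 in Bm MSC and 543 against 456 in Ad MSC. In Ad MSC the split at that fold turned to more lower genes: 230 higher and 313 lower on the Bm matrix, 57 and 146 on the Ad matrix and 162 and 294 on the NHDF matrix.

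Of the 5 arrays with the highest background signal, 4 were on the Bm matrix, arrays 2 and 3 of NHDF (2.586 and 2.635) and arrays 1 and 2 of Bm MSC (2.571 and 2.576), and the other was array 2 of NHDF on the Ad matrix (2.546), while the next highest array had 2.526. Without these 5, the Bm matrix had 434 called genes in NHDF, fewer than the 816 on the Ad matrix and 559 on the NHDF matrix, and 4156 in Bm MSC, against 2694 and 2059, with 1 Bm matrix array left in each cell type.

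Single arrays also moved these counts. In NHDF, the Ad matrix count was 698 and 2356 without its array 2 or 3 and 801 and 667 without plastic array 2 or 3. The Bm matrix count was 1719 without its array 3 and 2370 and 1867 without plastic array 2 or 3, and the NHDF matrix count was 287 without its array 3 and 243 and 226 without plastic array 2 or 3. In Bm MSC, the Ad matrix count was 1261 and 1247 without its array 1 or 2, and the NHDF matrix count 767 without its array 3 and 905 and 766 without plastic array 1 or 2. In Ad MSC, the Ad matrix count was 1134 without its array 1 and 1216 without plastic array 2.

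**Figure D3:**
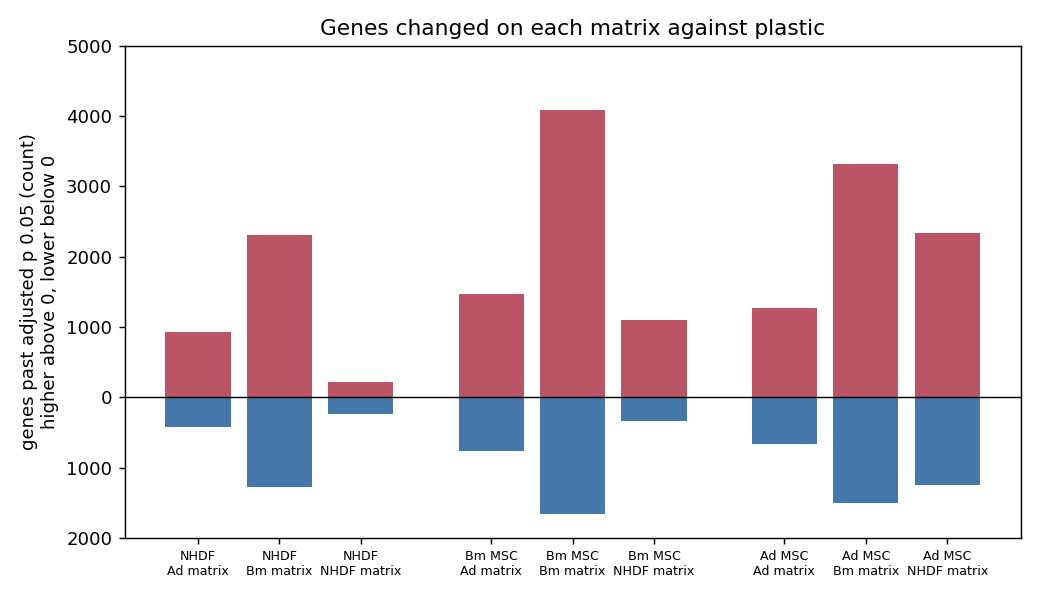
Number of genes called against plastic (y axis) for each matrix in each cell type, with bars above 0 for genes higher and below 0 for genes lower on the matrix. The Bm matrix has the tallest bars in each cell type (2306, 4083 and 3313 higher genes in NHDF, Bm MSC and Ad MSC), and with quantile normalization on top its genes in NHDF split into 1709 higher and 1852 lower.

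The cells' own matrix was compared with the matrices of the other cell types. In Ad MSC, PRR15 was 3.07-fold higher on the own matrix (log2 1.62, adjusted p = 6.2e-11), CEMIP 2.76-fold (log2 1.46), OXTR 1.98-fold and MEST 1.9-fold higher, and MMP1 1.85-fold lower (log2 -0.89). In Bm MSC, CXCL8 was 1.94-fold lower on the own matrix (log2 -0.95, SE 0.11, adjusted p = 5.6e-06), the focal adhesion gene NEDD9 1.59-fold and IER3 1.44-fold lower, and PGF, a growth factor of the VEGF family, 1.52-fold and KRT7 1.39-fold higher. In NHDF, INSIG1 was 1.46-fold higher on the own matrix (log2 0.55, SE 0.06, adjusted p = 1.8e-05) and DIRAS3 1.5-fold, BAMBI 1.48-fold, PGF 1.31-fold and IGFBP6 1.23-fold lower. In a fit to the NHDF arrays alone none of these 5 was called (adjusted p = 0.0538 for INSIG1), and without the 5 arrays of highest background INSIG1 was the only gene called. Without array 2 on the NHDF matrix DIRAS3, PGF and IGFBP6 were not called (adjusted p = 0.0501, 0.0501 and 0.0602), nor was PGF without array 1 (adjusted p = 0.0581) or DIRAS3 without array 3 (adjusted p = 0.0741).

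The own matrix comparison called 170 genes in NHDF (36 higher, 134 lower), 1573 in Bm MSC (1295 higher, 278 lower) and 521 in Ad MSC (265 higher, 256 lower). At a fold of at least 1.5 the split was 11 higher and 16 lower in Bm MSC and 40 and 17 in Ad MSC. Quantile normalization on top gave 44 higher and 45 lower in NHDF and 703 and 305 in Bm MSC. In a fit to the NHDF arrays alone limma called 0 genes, with 2009 at an unadjusted p under 0.05. The NHDF count was 12, 3 and 7 without array 1, 2 or 3 on the NHDF matrix, 88, 39 and 1080 without array 1, 2 or 3 on the Ad matrix, and 1920, 58 and 47 without array 1, 2 or 3 on the Bm matrix. In Bm MSC it was 830 and 555 without array 1 or 2 on the Ad matrix, 240 and 1042 without array 2 or 3 on the Bm matrix, 974 without array 2 on the NHDF matrix and 192 without the 5 arrays of highest background. In Ad MSC it was 226 and 229 without array 2 or 3 on the Ad matrix.

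HOX genes, which mark the position of a cell along the body axis, differed between the cell types. HOXB3 was 25.7-fold higher in Bm MSC (log2 4.68, SE 0.05) and 33.6-fold higher in Ad MSC (log2 5.07, SE 0.05) than in NHDF, HOXB7 14.6-fold and 16.2-fold, and HOXC8 9.55-fold and 23.1-fold, over 12, 11 and 12 arrays of NHDF, Bm MSC and Ad MSC. Of 18 HOX genes 14 were higher and 1 lower in Bm MSC than in NHDF (the same adjusted over the list alone; adjusted p = 1.1e-05, and 0.00307 with an estimated correlation). Likewise 14 were higher and 1 lower in Ad MSC under both adjustments (adjusted p = 2e-08, and 0.000368 with an estimated correlation).

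The genes with the largest differences from NHDF in Bm MSC were HAPLN1, which links aggrecan to hyaluronan (165-fold higher, log2 7.37, SE 0.07), SHISA2 (51.1-fold), ADGRG7 (42.6-fold), the adhesion molecule VCAM1 (34.2-fold), ABI3BP (29.1-fold) and the cytokine gene LIF (27.8-fold). Higher in NHDF were the matrix protease MMP3 (211-fold, log2 -7.72, SE 0.07), SSTR1 (182-fold), ALDH1A1, an enzyme of retinoic acid synthesis (153-fold), S100A4 (78.2-fold), the tissue factor gene F3 (73.9-fold) and MAB21L1 (73.2-fold). Of 20 growth factor genes 16 were higher and 4 lower in Bm MSC (the same adjusted over the list alone; adjusted p = 3e-06, and 0.000392 with an estimated correlation). Of 19 collagen processing genes 18 were higher and 0 lower (the same adjusted over the list alone; adjusted p = 2.9e-07, and 0.155 with an estimated correlation). Of 35 cell cycle genes 32 were lower and 2 higher (the same adjusted over the list alone; adjusted p = 9e-10, and 0.112 with an estimated correlation).

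In Ad MSC, MFAP5, a microfibril protein, was 82-fold higher than in NHDF (log2 6.36, SE 0.05), the prostacyclin synthase PTGIS 37.8-fold, AKAP19 33.5-fold, ALDH1A3 31.9-fold and the angiopoietin receptor TEK 29-fold. ALDH1A1 was 150-fold higher in NHDF, TFAP2A 23-fold, FLT1 18.9-fold, FOXF1 18.2-fold, GAL 17.6-fold and TCIM 13.7-fold. Chondrogenic genes were higher in Ad MSC in 5 of 6 and lower in 0 (the same adjusted over the list alone; adjusted p = 0.000759, and 0.037 with an estimated correlation). Proteoglycans were higher in 17 of 19 and lower in 1 (the same adjusted over the list alone; adjusted p = 2.9e-06, and 0.0568 with an estimated correlation). Cell cycle genes were lower in 33 of 35 and higher in 0 (the same adjusted over the list alone; adjusted p = 1.3e-09, and 0.082 with an estimated correlation).

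Between the mesenchymal stem cells, SHISA2 (48.2-fold, log2 5.59, SE 0.05), ADGRG7 (44.3-fold), VCAM1 (33.2-fold), PTN (12.6-fold), EFNB2 (12.2-fold) and TGM2 (11.9-fold) were higher in Bm MSC. In turn, S100A4 (79.3-fold, log2 -6.31, SE 0.04), MMP3 (65.4-fold), IL13RA2 (54.2-fold), SSTR1 (50.8-fold), PTGIS (41.6-fold) and EPB41L3 (36.2-fold) were higher in Ad MSC. Antigen presentation genes were higher in Bm MSC in 13 of 13, among them HLA-B (3.13-fold), HLA-F (2.8-fold) and the immunoproteasome gene PSMB9 (2.72-fold), and lower in 0 (the same adjusted over the list alone; adjusted p = 7e-07, and 0.0202 with an estimated correlation). Growth factors were higher in Bm MSC in 15 of 20 and lower in 4 (the same adjusted over the list alone; adjusted p = 0.000562, and 0.00734 with an estimated correlation). Targets of p53 were lower in Bm MSC in 19 of 20 and higher in 1 (the same adjusted over the list alone; adjusted p = 2.9e-08, and 0.00734 with an estimated correlation). HOX genes were lower in 12 of 18 and higher in 2 (13 and 2 adjusted over the list alone), HOXB5 being 3.6-fold and HOXB8 3.11-fold higher in Ad MSC (adjusted p = 0.000162, and 0.00734 with an estimated correlation). Adipogenic genes were lower in Bm MSC in 7 of 11 and higher in 1 (the same adjusted over the list alone), with the fatty acid transporter CD36 6.87-fold and PPARG, the main regulator of fat cell formation, 4.94-fold higher in Ad MSC (adjusted p = 0.0177, and 0.0496 with an estimated correlation).

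In total 8041 genes differed between Bm MSC and NHDF (3894 higher, 4147 lower in Bm MSC), 8166 between Ad MSC and NHDF (3446 higher, 4720 lower in Ad MSC) and 7224 between Bm MSC and Ad MSC (4434 higher, 2790 lower in Bm MSC). At least 1.5-fold differences numbered 1526 (889 higher, 637 lower), 1531 (840 and 691) and 1018 (507 and 511). Of the lists, 17, 22 and 13 passed camera, and 2, 2 and 5 kept the call with an estimated correlation. With the poly-A signal as a covariate, which separates the cell types, 4901 genes were called between Bm MSC and NHDF and 3597 between Bm MSC and Ad MSC (1737 higher, 1860 lower).

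Genes that stood out in the cells that made a matrix were then followed in the cells grown on it. The 100 genes highest in NHDF over Bm MSC on plastic were lower in Bm MSC on the NHDF matrix than on the Bm matrix, with a median log2 of -0.1, 25 genes lower and 6 higher (adjusted p = 0.0187, and 0.616 with an estimated correlation). The call ended without plastic array 1 of NHDF (median -0.08, adjusted p = 0.0519) or plastic array 2 of Bm MSC (median -0.07, adjusted p = 0.0583), and with the stricter filter (adjusted p = 0.123). In NHDF, genes of Bm MSC on the Bm matrix had a median of 0.07 (adjusted p = 0.278) and genes of Ad MSC on the Ad matrix one of 0.1 (adjusted p = 0.24). With quantile normalization on top both passed (adjusted p = 0.017 and 2.9e-06), as they did without the filter (adjusted p = 0.0125 and 7.6e-05). The Ad MSC genes also passed without array 3 of NHDF on the Ad matrix (adjusted p = 0.0438) or array 1 on the NHDF matrix (adjusted p = 0.0277). In Bm MSC, genes of Ad MSC on the Ad matrix had a median of -0.03 while the test pointed up (adjusted p = 0.278). In Ad MSC, genes of NHDF and of Bm MSC had medians of -0.0075 and -0.00417 on those cells' matrices (adjusted p = 0.278 and 0.24), the first with a mean of 0.03.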

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

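The tests with the array background, the array spread or the poly-A signal as added settings, and the exact permutation of list medians, were chosen only after the data were seen. The interaction, the splits of the samples, the matched random lists and the source transcripts were chosen before their results were seen. The background test in Ad MSC was dropped after its ratio of 1.3 was seen, because none of the 5 arrays of highest background was an Ad MSC array.

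The response to the matrices differed between cell types for 829 genes in Bm MSC against NHDF, 1526 in Ad MSC against NHDF and 697 in Bm MSC against Ad MSC, by limma's interaction test. By size and sign, the differences (log2) between Bm MSC and NHDF were 2.34 for MMP1, 2.7 for CXCL8, 1.35 for CAMK2N1, 1.55 for IGF2BP3 and 1.8 for CXCL1. Between Ad MSC and NHDF they were -1.94 for MEX3B, -2.52 for SCRG1, -2.43 for PRR15, -1.31 for TSC22D3 and -1.24 for ANKRD37. Between Bm MSC and Ad MSC they were 1.39 for ATF5, 1.65 for SFRP1, 1.92 for PI16, 1.52 for MEX3B and 1.48 for MMP1. Of 100 splits of the arrays among the substrates, 3, 2 and 4 gave as many genes. These splits shuffle the substrates within both cell types, so they stand for no matrix effect at all. They cannot decide whether the effects differ between cell types. The highest other splits gave 3042, 3068 and 1554 genes, several times the real count in the first case, which points to a structure of the samples, and the arrays that these splits set apart were not examined.

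The list test for the same contrasts called 17, 18 and 9 lists, also as a difference between cell types. For these counts chance cannot be excluded, since 9, 8 and 57 of 100 splits gave as many lists, with highest other splits of 22, 21 and 25.

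Contractile genes and fibrillar collagens were lower on the matrices in the 3 cell types by camera, but with an estimated correlation the collagens lost the call in NHDF (adjusted p = 0.153) and Ad MSC (adjusted p = 0.0743), and their permutation in NHDF gave an adjusted p of 0.065. A difference in array spread is argued against for all but the contractile genes in Ad MSC, since the list medians with the spread as a covariate kept at least 0.94 of their size, and unequal RNA input is argued against by a smallest ratio of 0.715 with the poly-A signal as a covariate. Compression of bright signals is argued against too, because the highest percentile of the 6 medians among 10000 random lists of like brightness was 0. For the contractile genes in Ad MSC the array spread stays open: the ratio was 1.02, but its bootstrap SD over the members was 0.718. They were set apart only after the spread test over all lists and cell types together could not decide. A response of the cells to the matrix remains a hypothesis, with tests on the same data that raised it.

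The Bm matrix had the most called genes against plastic in each cell type, with 2.63, 2.59 and 1.34 times the next highest count in NHDF, Bm MSC (where the next group held 2 arrays) and Ad MSC, but at a fold of at least 1.5 only 206 against 163, 455 against 414 and 543 against 456. Transcripts left by source cells are argued against as the whole cause, not a part, for genes at least 1.5-fold higher on the Bm matrix. Of these, 52.3% (binomial SD 4.78) in NHDF were lower in Bm MSC than in the receiving cells on plastic. In Ad MSC 42.6% (SD 3.26) were, and 54.7% and 41% of all genes. For smaller changes the share was not taken, and Bm MSC on its own matrix could not be tested. The 100 genes of Bm MSC in NHDF had a median of 0.0685 (13 higher, 3 lower, adjusted p = 0.278). They passed upward with quantile normalization on top or without the filter (adjusted p = 0.017 and 0.0125). The array spread is argued against in NHDF, where the ratio with it as a covariate was 3.45, and stays open in Bm MSC and Ad MSC (1.16 and 1.08). The array background stays open in NHDF and Bm MSC, where the ratio without the 5 arrays of highest background was 0.532 and 1.54 with only 1 Bm matrix array left in each, as does the matrix itself, a difference that the design names and that was not tested against these.

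Cell cycle genes were higher on the matrices in Bm MSC and Ad MSC by camera, and both calls were lost with an estimated correlation (adjusted p = 0.137 and 0.0743). The array spread (smallest ratio of list medians 0.875) and RNA input (0.97) are argued against by the covariate fits. A general upward shift of genes of this brightness is argued against as well, because the lowest percentile of the 2 medians among random lists of like brightness was 100. Every explanation tested here had a value against it, so a response of the cell cycle to the matrices is a candidate explanation, found and tested on the same data. A different density of the cells on the substrates at harvest was not tested.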

How the results depend on the processing

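The added fits with the array spread, the poly-A signal or without the 5 arrays of highest background were chosen after seeing the data, and the other settings before. Here a count kept its side when it stayed within 1.5-fold of the main count, whatever its split into higher and lower genes. A source gene test did so when its direction and call stayed. The genes changed alike thus counted as kept with quantile normalization, though their split went from 508 and 244 to 361 and 327. Of the 40 main results, all 40 kept their side under eBayes with trend and robust. Under median centring, the mean of probe sets and the stricter filter 39 did, and 38 with the replicate block. The number was 36 with quantile normalization on top, 34 with the poly-A signal, 33 without the filter, 32 with the array spread and without the 5 arrays of highest background, 32 of 39 in fits to the compared cell types and 22 with array weights. The counts of NHDF rested most on single arrays. Unless said otherwise, the cause was not tested. Of 443 values for named genes, all 443 kept their direction and call under eBayes with trend and robust, array weights and median centring. The number was 442 with quantile normalization on top, 440 with the array spread, 439 with the mean of probe sets and with the poly-A signal, 438 without the filter, 435 without the 5 arrays of highest background and 434 in fits to the compared cell types. Of 414 that could be tested under the stricter filter, 414 did. With arrays left out in turn, 36 of 7444 lost the call.

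Without the filter, the own matrix called 59 genes in NHDF and 993 in Bm MSC, and the F-test 1018, 1091 and 536 in NHDF, Bm MSC and Ad MSC. The source genes in NHDF passed with medians of 0.0517 on the Bm matrix and 0.107 on the Ad matrix. The NHDF genes in Bm MSC on the NHDF matrix lost the call with the stricter filter (-0.0977, adjusted p = 0.123) and with the mean of probe sets (-0.0612, adjusted p = 0.262). Quantile normalization on top gave 89 genes for the own matrix in NHDF and 1008 in Bm MSC, and source gene medians that passed of 0.0905 on the Bm and 0.115 on the Ad matrix in NHDF. Median centring turned the median of Bm MSC genes in Ad MSC to 0.00917 (adjusted p = 0.174).

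Array weights raised most counts. For the matrices in NHDF they gave 2643. They gave for single matrices 3654 (NHDF on Ad), 823 (NHDF on NHDF), 2789 (Bm MSC on NHDF), 4380 (Ad MSC on Ad) and 5711 (Ad MSC on NHDF). For the own matrix they gave 1652, 4274 and 2018 in NHDF, Bm MSC and Ad MSC, for the F-test 3248, 4989 and 3304, for genes changed alike 1245 and for the interactions 1497 (Bm MSC and NHDF), 3269 (Ad MSC and NHDF) and 2626 (Bm MSC and Ad MSC). The NHDF genes in Bm MSC lost the call (-0.0896, adjusted p = 0.154), and those in Ad MSC turned to 0.00939 (adjusted p = 0.29).

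With the replicate number as a block, the own matrix called 66 genes in NHDF and the pair of Bm MSC and Ad MSC 4789, and FLT1 between these turned to 0.0782 (adjusted p = 0.592). The replicate numbers do not pair the samples: the median correlation of deviations between same-numbered arrays was -0.067 in NHDF (4 of 18 pairs over 0.1), -0.0225 in Bm MSC (2 of 15) and 0.0093 in Ad MSC (5 of 18). The block changed no other call among these results.

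A fold of at least 1.5 as well leaves fewer genes by construction: 125, 290 and 368 for the matrices in NHDF, Bm MSC and Ad MSC, 163, 206 and 82 on the Ad, Bm and NHDF matrix in NHDF, 414, 455 and 150 in Bm MSC and 203, 543 and 456 in Ad MSC. It left 2, 27 and 57 for the own matrix, 1526, 1531 and 1018 for the pairs Bm MSC and NHDF, Ad MSC and NHDF and Bm MSC and Ad MSC, 160, 248 and 188 for their interactions, and 56 for genes changed alike. In fits to the compared cell types alone, NHDF had 825 genes for the matrices, 739, 1929 and 212 for the single ones, 4 in the F-test and 0 for the own matrix (2009 at an unadjusted p under 0.05 in limma), and Ad MSC 425 in the F-test.

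An estimated correlation left 5, 7 and 6 lists for the matrices, 2, 2 and 5 for the pairs and 2, 2 and 2 for the interactions. Fry called 30 and 29 lists in Bm MSC and Ad MSC, 36, 43 and 35 for the pairs and 18 for the interaction of Bm MSC and Ad MSC. With source lists of 200 genes the medians in Ad MSC turned to 0.00417 for Bm MSC genes (adjusted p = 0.369) and 0.0222 for NHDF genes (adjusted p = 0.347), and with 50 the latter to 0.046 (adjusted p = 0.11), while NHDF genes in Bm MSC lost the call (-0.109, adjusted p = 0.0833).

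With the array spread as a covariate, Bm MSC had 2357 genes for the matrices, 2612 on the Bm matrix, 868 on the NHDF matrix and 526 for the own matrix, and NHDF had 713 on the Ad matrix and 12 for the own matrix. It left 493 genes changed alike, and Ad MSC genes in Bm MSC turned to 0.0229 (adjusted p = 0.281). With the poly-A signal, the pairs with Bm MSC had 4901 (NHDF) and 3597 (Ad MSC) genes, the F-test 391 in Ad MSC, the own matrix 271 in NHDF, the list test 15 for the interaction of Bm MSC and Ad MSC, and NHDF genes in Ad MSC turned to 0.0251 (adjusted p = 0.218). Without the 5 arrays of highest background, NHDF had 816 genes on the Ad and 434 on the Bm matrix, 19 in the F-test and 1 for the own matrix. Bm MSC had 1003 in the F-test and 192 for the own matrix, Ad MSC 1604 in the F-test, and the interaction of Bm MSC and Ad MSC 1087.

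With each array left out in turn, 661 of 724 values stayed on their side. For the matrices the lowest and highest counts were 642 and 2237 in NHDF, 2597 and 4511 in Bm MSC and 3253 and 4434 in Ad MSC. On the Ad, Bm and NHDF matrix they were 667 and 2356, 1719 and 4608, and 226 and 527 in NHDF, 1247 and 2288, 4364 and 5700, and 766 and 1716 in Bm MSC, and 1134 and 1956, 3738 and 4890, and 2745 and 3795 in Ad MSC. The F-test gave 205 to 3564, 734 to 1677 and 368 to 1284, and the own matrix 3 to 1920, 240 to 1535 and 226 to 618. Genes changed alike numbered 386 to 973, and the interactions 537 to 1021 (Bm MSC and NHDF), 1159 to 1756 (Ad MSC and NHDF) and 463 to 815 (Bm MSC and Ad MSC). The pairs numbered 7797 to 8215 (Bm MSC and NHDF), 8021 to 8196 (Ad MSC and NHDF) and 6830 to 7302 (Bm MSC and Ad MSC). The lists numbered 12 to 16, 14 to 20 and 13 to 18 for the matrices in NHDF, Bm MSC and Ad MSC. For the pairs in the same order they numbered 17 to 18, 22 to 22 and 13 to 14, and for the interactions 13 to 18, 16 to 20 and 4 to 12. The source gene medians lay between 0.0507 and 0.138 for Ad MSC genes and between 0.0418 and 0.0969 for Bm MSC genes in NHDF, and between -0.131 and -0.0733 for NHDF genes and -0.0558 and -0.0159 for Ad MSC genes in Bm MSC. In Ad MSC, NHDF genes lay between -0.0125 and 0.0169 and turned upward without Ad MSC array 1 (0.00875) or 3 (0.0124) on the NHDF matrix or array 2 (0.0108) or 3 (0.0169) on the Ad matrix. Bm MSC genes there lay between -0.0262 and 0.00542 and turned without array 2 on the Bm matrix (0.00542).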

Other observations

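The exact permutation tests of list medians were chosen only after the result was seen, and the limma and camera tests and the splits of the samples before.

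Of 19 interferon genes, which answer viral signals, 8 rose and 1 fell on the matrices in Bm MSC, and 4 rose and 6 fell in Ad MSC (8 and 1, and 4 and 7, adjusted over the list alone). The list passed camera in neither (adjusted p = 0.121 and 0.212). The difference between these cell types did pass, with a higher effect in Bm MSC for 6 of 19 genes and a lower one for 0 (8 and 0 adjusted over the list alone; median 0.2, adjusted p = 0.000652, and 0.12 with an estimated correlation). Cytosolic ribosomal protein genes rose in 9 of 31 in Bm MSC and 6 in Ad MSC and fell in 0 (likewise adjusted over the list alone). Their medians of 0.06 lay near those of all genes (0.0625 and 0.0436), and camera passed neither (adjusted p = 0.0554 and 0.195). Exact permutation, which ignores other genes, passed them (adjusted p = 0.0237 and 0.0355). Their median effect was higher in Bm MSC than in NHDF by 0.08 (adjusted p = 0.00111, and 0.173 with an estimated correlation). Markers of endothelial cells, keratinocytes, melanocytes and blood cells passed camera for the matrices in no cell type (smallest adjusted p 0.101). By exact permutation of the list median, melanocyte markers did pass in Bm MSC, downward (median -0.16, adjusted p = 0.046), and blood cell markers did not (median -0.23, adjusted p = 0.0651).

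Between cell types, lysosome genes were higher in Bm MSC than in NHDF in 17 of 19 and lower in 1 (the same adjusted over the list alone; adjusted p = 0.000316, and 0.227 with an estimated correlation). Chemokines and cytokines were lower in Bm MSC than in Ad MSC in 15 of 21 and higher in 6 (the same adjusted over the list alone; adjusted p = 0.000733, and 0.111 with an estimated correlation). Osteogenic genes were higher in Bm MSC than in Ad MSC in 4 of 5, with DLX5 5.27-fold and RUNX2, the main regulator of bone formation, 2.01-fold higher, and lower in 0 (the same adjusted over the list alone; adjusted p = 0.0222, and 0.0553 with an estimated correlation). Replication-dependent histones were lower in Ad MSC than in NHDF in 3 of 3 (the same adjusted over the list alone; adjusted p = 0.0397, and 0.247 with an estimated correlation).

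Exact permutation of the matrix and plastic arrays gave p = 0.00455 (adjusted p = 0.0326) for the median of the contractile genes in NHDF, 0.00606 (adjusted p = 0.0237) in Bm MSC and 0.00455 (adjusted p = 0.0217) in Ad MSC, each the smallest these permutations can give. For the fibrillar collagens the values were 0.0136 in NHDF (adjusted p = 0.065), 0.00606 in Bm MSC and 0.00455 in Ad MSC. For the cell cycle genes they were 0.0409 in NHDF (adjusted p = 0.135), 0.00606 in Bm MSC and 0.00455 in Ad MSC. Other lists passed as well, among them focal adhesion, metallothioneins and p53 targets in NHDF (adjusted p = 0.0326 each). Some lists that kept their camera call with an estimated correlation did not pass: YAP and TAZ targets (adjusted p = 0.065) and growth factors (0.182) in NHDF, and hypoxia and glycolysis (0.397) and the unfolded protein response (0.151) in Ad MSC.

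Other splits of the samples were counted for each comparison. For the matrices against plastic, chance can be excluded in NHDF (1546 genes, highest other 2902, 4 of 100 splits as large), Bm MSC (4316, highest other 3281, 1 of 100) and Ad MSC (4378, highest other 2894, 1 of 100). The highest other split in NHDF and Bm MSC set apart the 3 Bm matrix arrays. For the lists past camera it cannot be excluded, at 14 lists against a highest other of 18 (7 of 100), 15 against 21 (28 of 100) and 16 against 23 (34 of 100). Genes changed alike numbered 752 against 0 (1 of 100), with at most 79 at an unadjusted p under 0.05 in limma in another split. These splits remove all matrix effects, so they cannot test the overlap.

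Among the matrices, chance cannot be excluded in NHDF (1722 genes against a highest other of 2439, 6 of 100) and can be excluded in Bm MSC (1739 against 771) and Ad MSC (1018 against 844). For the own matrix it cannot be excluded in NHDF, where 10 of 84 splits gave as many as 170 genes, and it can be excluded in Bm MSC (1573 against 538, 1 of 56). In Ad MSC (521 against 925, 2 of 84) another split called more genes, so chance is argued against but not excluded. The highest other split in NHDF called 3562 genes and set apart exactly the 3 NHDF arrays of highest background, which points to a structure of the samples, and that in Ad MSC set apart the Bm matrix arrays. Between cell types chance can be excluded for the genes, at 8041 against 6061, 8166 against 4721 and 7224 against 4398 for Bm MSC with NHDF, Ad MSC with NHDF and Bm MSC with Ad MSC. For the lists it can be excluded in the last pair (13 against 15, 2 of 100) and not in the others (17 against 20, 10 of 100, and 22 against 23, 7 of 100).

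For a single matrix against plastic, 3 against 3 arrays give 10 splits, too few for a share under 0.05. The real and highest other counts were 1359 and 137 in NHDF on the Ad matrix, 3577 and 658 on the Bm matrix and 442 and 0 on the NHDF matrix, the last with 926 genes at an unadjusted p under 0.05 in limma. In Bm MSC they were 5751 and 0 on the Bm matrix, the latter with 2313 genes at an unadjusted p under 0.05 in limma, and 1442 and 1 on the NHDF matrix. In Ad MSC they were 1938 and 1, 4811 and 2, and 3594 and 1 on the Ad, Bm and NHDF matrix. The 10 splits were also too few for the genes of the source cells, whose medians had sizes of 0.0685 against a highest other of 0.0743 and 0.0987 against 0.101 in NHDF on the Bm and Ad matrix. The sizes were 0.0992 against 0.086 in Bm MSC on the NHDF matrix, and 0.0075 against 0.0195 and 0.00417 against 0.0297 in Ad MSC on the NHDF and Bm matrix. Splits of Bm MSC on the Ad matrix, with 2 arrays, were not counted.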
